A study of Escherichia coli str. K-12 substr. MG1655 with 2 samples.

How the data were processed

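Transcript levels were measured by RNA sequencing in Escherichia coli K-12 MG1655, the reference laboratory strain of the species. The labels describe 1 group of 2 libraries grown at 37 °C, numbered as replicates 1 and 2. Per the labels' protocols, cells were taken in mid-exponential growth at an optical density (OD) of about 0.6. RNA was extracted with the RNAsnap method, ribosomal RNA was removed with a Ribo-Zero kit for bacteria, and 4 µg of the purified RNA was cut to fragments of about 300 bases. Libraries were made from 50 ng of fragments with a TruSeq stranded kit, which keeps the strand of origin by marking the second strand with dUTP, and were read on an Illumina MiSeq. Nothing in the labels says whether the replicates came from separate cultures. The labels differ on the medium. The sample titles, the extraction protocol and the name of the deposited table give LB, a rich medium of tryptone, yeast extract and salt. The growth protocol instead has the overnight LB culture diluted 1:100 into minimal medium.

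The deposited values are RPKM (reads normalised to gene length in kilobases and to sequencing depth), per the file headers, and the table used here gives 1 value per feature for the whole group. The submitters' processing notes name CASAVA 1.4 without saying what it was used for. The aligner, counting tool, genome build, annotation, treatment of reads that match several places, and the way in which the 2 libraries were combined are not given in the sources used here. The table holds 4240 features named by b-number locus tags. Of these, 4236 were matched to gene symbols, types and lengths in a RefSeq gene table of assembly ASM584v2, and 4 were not. As the build of the deposited table is not named, no coordinates are given. The RefSeq table was used for names, gene order and gene lengths.

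The depth was read from the lowest values. RPKM multiplied by gene length in kilobases is proportional to reads, and for 70 features of up to 400 bases with a product under 0.45 these products clustered at sums of 2 step sizes, 0.0616 and 0.0713. With the rounding of the deposited RPKM (0.005) as tolerance, 80.0% of the 70 products lay on whole sums of the 2 steps. A single step size gave 24.3%, and the best of 20 refits to randomly moved values gave 40.0%. Those refits tried a coarser grid of step sizes than the fit itself, which can lower their share. The 40.0% is therefore not a like comparison for the 80.0%. An unweighted average of 2 libraries of about 8120000 and 7010000 reads has this spacing, and these depths were used under that assumption, which was chosen after the data were examined. Which replicate was the deeper is not known. A read was then worth 0.0661 RPKM times kilobases on average, and approximate reads per feature were computed from that. On simulated libraries of 9000000 and 6000000 reads over 4236 features the procedure returned 8990000 and 6010000. These simulated depths lay further apart than the fitted ones, so recovery of depths as close as those was not tested. Summed over all matched features the values amount to 16500000 reads, against 15100000 for the sum of the depths, and this difference was not resolved. Exact Poisson 95% intervals computed from these approximate reads cover counting error only. Reads carry no molecular identifiers, so they are not independent molecules.

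With 1 group and 1 value per feature, no comparison between conditions and no replicate error could be computed. The agreement between replicates, and the results without each replicate, were therefore not computed. Genes were instead compared within the transcriptome. Before the data were examined, 52 gene lists (859 genes, 856 with a value), 36 operons in transcript order and 10 toxin-antitoxin pairs were written from textbook knowledge. For each list the median of log2(RPKM + 1) was placed among the medians of 10000 random lists of the same size drawn from all features. A median at or above the 99th percentile is called high and one at or below the 1st percentile low. These percentiles describe this set of values and are not p-values. For genes drawn independently, chance alone would give about 1.04 calls over 52 lists. Many lists hold operons, whose members are alike, so chance calls are more frequent than that. Random lists in which each run of neighbouring members was replaced by a random run of as many adjacent genes were therefore tried as well. The same was done for the standard deviation of log2(RPKM + 1) over the members of each operon, called even at or below the 1st percentile of random sets. Antitoxins were compared with toxins by an exact sign-flip permutation test over pairs. Spearman's correlation was computed over neighbouring genes in RefSeq order. A comparison of neighbours by strand was not made, as strand is not part of the gene table used here, and one by distance from the replication origin was not made, as it needs a named build. In simulations on 4240 features, 9 of 10 lists drawn from the upper part of the distribution were called high, 10 of 10 from the lower part low, and 3 of 60 random lists either.

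The rule for named genes, also written before the data were examined, takes the 10 highest features, the highest and lowest member of each list and the member nearest its median, the second highest member of each amino acid biosynthesis list, the first and last gene of each operon, and all toxin-antitoxin pairs. Of the operons, only some are described singly, and these were chosen after their values were seen. So were the other genes named in the text that this rule does not cover. Alternatives changed the pseudocount to 0.1, the detection limit, the filter on low values, the summary from median to mean, and the source of random lists (matched on gene length, or for operons matched on level or made of adjacent genes). Alternatives chosen after the data were examined left out features listed at 0 or restricted the lists to protein-coding features, or kept the runs of neighbouring genes in the random lists. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.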

Results

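The series recorded the transcript levels of Escherichia coli K-12 MG1655 growing at 37 °C, in 1 group of 2 stranded RNA sequencing libraries. The deposited table gave 1 RPKM value for each of 4240 features, of which 4095 were protein-coding genes, 64 transfer RNA genes, 56 non-coding RNA genes and 13 ribosomal RNA genes. The spacing of the lowest values corresponded to an average of libraries with about 8120000 and 7010000 reads. The median feature had about 520 reads, 3065 features had more than 100 reads, and 332 features (7.84% of those matched to a gene) had fewer than 10. At 100 reads the counting error is 10% of the value. No value carries a replicate error, as the table used here holds 1 value per feature, so the comparisons below are between genes of the averaged transcriptome, and the intervals given cover counting error only.

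**Figure D1:**
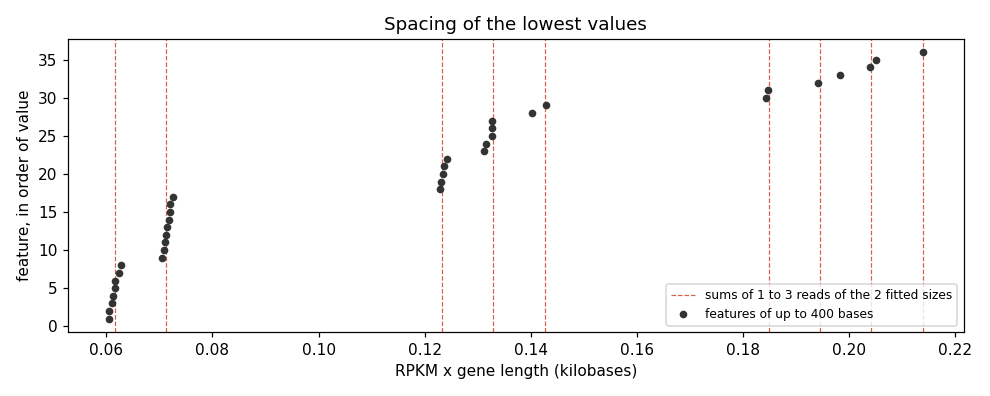
RPKM multiplied by gene length in kilobases (horizontal axis) for the features of up to 400 bases with the lowest values, each a point, in order of value (vertical axis). Dashed lines mark sums of 1 to 3 reads of the fitted sizes 0.0616 and 0.0713, and the points gather at these lines with empty stretches between them.

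Transcripts were recorded for most of the genome, and a small number of features held much of the total. Of the 4240 features, 3919 (92.4%) had an RPKM of at least 1, including 3819 of the 4095 protein-coding genes (93.3%). The median RPKM was 44.1, and the middle 50% of features lay between 6.43 and 175. The 10 highest features held 24.97% of the summed RPKM and the 100 highest held 59.6%. Among protein-coding genes alone, the 10 highest held 15.7%. A feature listed at 0 was not read as untranscribed: 124 features had that value, and they included rpmA (ribosomal protein L27) and ihfA (a subunit of the nucleoid protein IHF), which growing cells use.

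Of the 10 highest features, 6 were non-coding RNAs and 4 were protein-coding. The highest of all was ssrA, the transfer-messenger RNA that rescues stalled ribosomes, at 163339 RPKM (95% Poisson interval 163001 to 163678), which corresponded to 5.45% of assigned reads. It was followed by cspA, an RNA chaperone of the cold shock family, at 64477 RPKM. Next came rnpB, the RNA of ribonuclease P, at 49930 RPKM, gcvB, a small RNA that represses amino acid and peptide transporters, at 36193 RPKM, and ssrS, the 6S RNA that binds RNA polymerase, at 25082 RPKM. The remaining members of the 10 were rpmI (ribosomal protein L35) at 20909, the tryptophanase leader peptide gene tnaC at 19990, the non-coding RNA gene tff at 19570, the valine transfer RNA gene valX at 18775 and rpmF (ribosomal protein L32) at 17136 RPKM. Values of features shorter than the RNA fragments depend on how fragments that reach beyond the gene were counted, which is not given in the sources used here. The value of valX may also depend on how reads shared between near-identical transfer RNA genes were assigned, as 29 of 64 transfer RNA genes were listed at 0.

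Of the 52 gene lists, 24 were called high, 4 low and 24 neither. Against random lists that kept runs of adjacent genes, 20 were called high and 3 low. Genes of protein synthesis were among those called high. The 54 ribosomal protein genes had a median of 3999 RPKM, with 53 above the median of all features. The exception was rpmA, listed at 0, and the member nearest the list's median was rpsM at 3974 RPKM. The 13 translation factors had a median of 1030 RPKM (frr, the ribosome recycling factor, held this value) and ran from prfC at 230 to the elongation factor G gene fusA at 5781 RPKM. All 22 aminoacyl-tRNA synthetase genes lay above the median of all features, between glnS at 78.3 and thrS at 2297 RPKM, with hisS at 514 RPKM near the list's median of 501. The medians of these 3 lists exceeded those of all 10000 random lists (percentile 100).

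**Figure D2:**
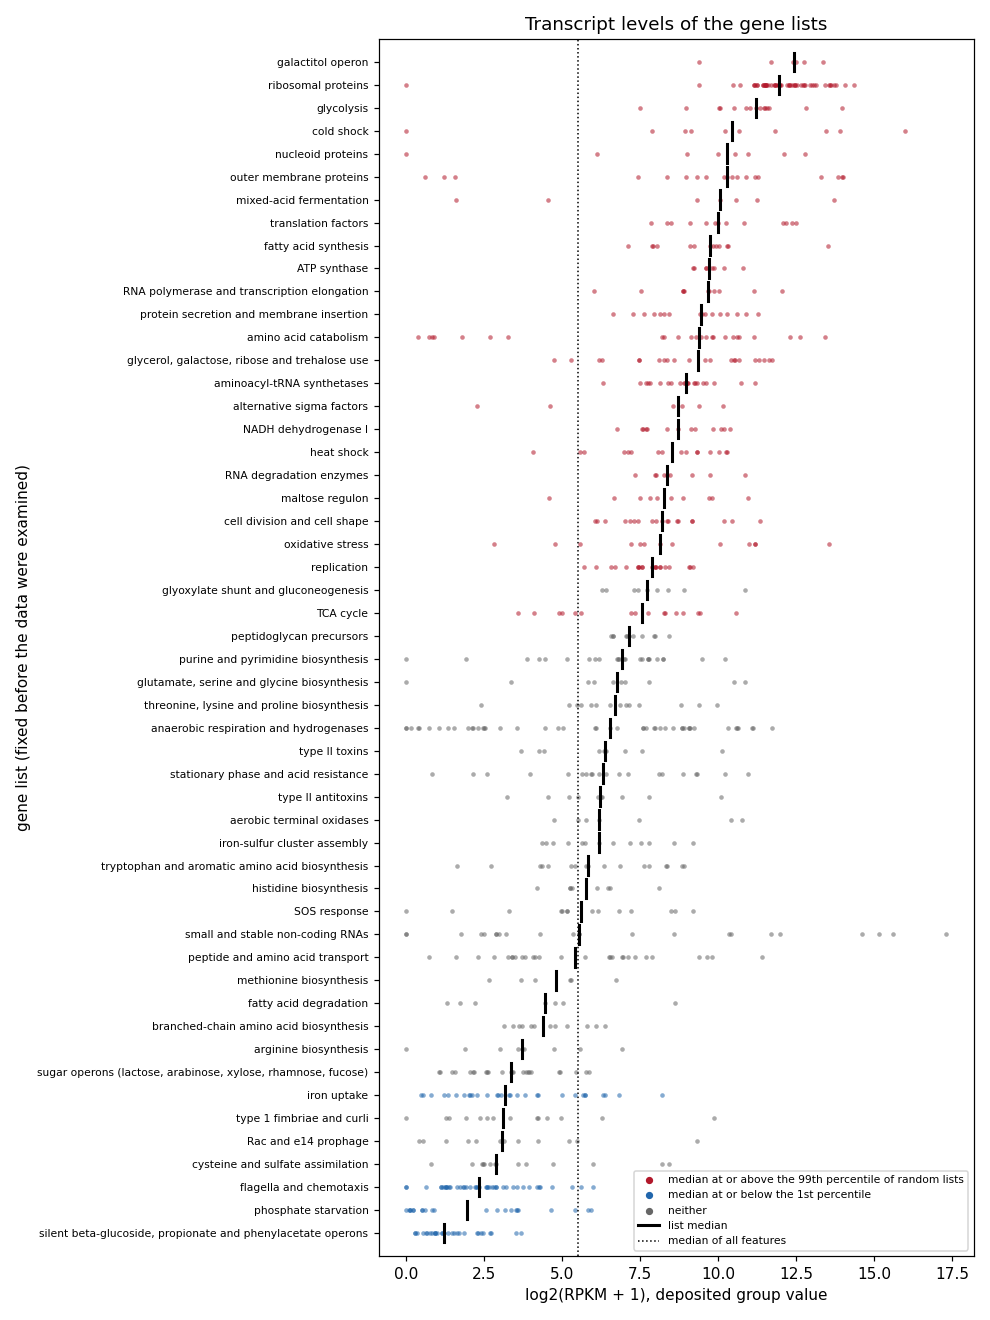
Transcript level as log2(RPKM + 1) on the horizontal axis for every measured member (points) of the 52 gene lists (rows, ordered by median, black bars); the dotted line is the median of all features, 44.1 RPKM. Red lists were called high, blue lists low and grey lists neither. The 4 blue lists are flagella, phosphate starvation, iron uptake and the list named silent beta-glucoside, propionate and phenylacetate operons.

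Genes of transcription, secretion, envelope and growth were also high. RNA polymerase and elongation factors had a median of 815 RPKM (rpoB), from greB at 63.8 to rpoA at 4221 (percentile 99.99). Alternative sigma factors had a median of 418 RPKM, with rpoH, the heat shock sigma factor, at 1130, rpoE at 377 and the flagellar sigma factor gene fliA at 3.83 (99.34). Their call was lost when the mean replaced the median (93.66) and when features listed at 0 were left out (98.98). Of the nucleoid proteins, 7 of 8 lay above the median of all features, led by hns at 7007 RPKM, with hupB at 1473 near the list's median of 1242 and ihfA listed at 0 (99.99). Secretion and membrane insertion genes had a median of 701 RPKM, from lspA at 98.1 to the translocon gene secY at 2463, with secA at 690 (100). Outer membrane protein genes had a median of 1232 RPKM (bamE), and spanned the porin ompC at 16550 and the porin ompG at 0.530 RPKM (100). Fatty acid synthesis genes had a median of 850 RPKM (fabI), from fabH at 137 to the acyl carrier protein gene acpP at 11826 (100). Replication genes, all 21 above the median of all features, had a median of 235 RPKM (dnaG), from ligA at 50.9 to holC at 588 (99.9). Cell division and shape genes, all 19 above it, had a median of 290 RPKM (ftsI), from mrdB at 65.7 to minE at 2573 (99.98). RNA degradation enzymes had a median of 326 RPKM (rppH), from orn at 160 to hfq, the small RNA chaperone, at 1845 (99.29). Peptidoglycan precursor genes, all 11 above the median of all features, were not called: their median was 141 RPKM (murI), from murC at 94.0 to murF at 340 (93.2).

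Energy metabolism combined high glycolytic and fermentative transcripts with low transcripts of some list members, such as sdhD and the lactate dehydrogenase gene ldhA. All 15 glycolysis and sugar phosphotransferase genes lay above the median of all features, with a median of 2399 RPKM (gpmM), from ptsG at 178 to the glyceraldehyde-3-phosphate dehydrogenase gene gapA at 15898 (percentile 100). Mixed-acid fermentation genes had a median of 1067 RPKM (focA). Of the 7 members, 5 lay above the median of all features, while ldhA, at 22.6 RPKM, and acs lay below it. The highest member of the list, the pyruvate formate-lyase gene pflB, stood at 13461 RPKM, and the lowest, the acetyl-CoA synthetase gene acs, at 2.04 (99.97). ATP synthase genes ranged only from atpC at 584 to atpG at 1779 RPKM, with atpB at 789 and a median of 839 (99.95, or 98.6 and not called against random runs of adjacent genes). The 13 genes of NADH dehydrogenase I had a median of 418 RPKM (nuoH), from nuoM at 107 to nuoE at 1343 (99.95, or 97.8 and not called against such runs). The TCA cycle list was called high, at a median of 187 RPKM with gltA at 213, but its members ranged from sdhD, a succinate dehydrogenase subunit, at 11.1 to the malate dehydrogenase gene mdh at 1518 (99.07). The call of this list ended, at the 98.46th percentile, when features under an RPKM of 1 were left out, and at 94.3 against random runs of adjacent genes. Glyoxylate shunt and gluconeogenesis genes had a median of 209 RPKM (glpX), from aceK at 76.3 to the phosphoenolpyruvate carboxykinase gene pck at 1861, and were not called (97.2).

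Respiratory genes differed widely between enzymes, including those that serve the same acceptor. The 7 aerobic terminal oxidase genes had a median of 71.7 RPKM (cyoC) and were not called (67.7), with 6 of 7 above the median of all features. The cytochrome bd oxidase, which has the higher affinity for oxygen, had cydA at 1725 and cydB at 1368 RPKM. The 5 genes of the cytochrome bo oxidase lay between cyoD at 25.6 and cyoA at 174 RPKM, and cydA exceeded cyoB 38.9-fold. The anaerobic respiration and hydrogenase list had a median of 91.7 RPKM (hybF) and was not called (96.6), with 26 of 47 members above the median of all features. It was called high when features under an RPKM of 1 were left out (99.99), a filter that also removes low members of the list itself. With the mean in place of the median it lay at 82.75, and against random runs of adjacent genes at 88.4. Its highest member was the nitrate reductase gene narG at 3371 RPKM, and the gene narY of the second nitrate reductase was listed at 0. The fumarate reductase gene frdA, at 1522 RPKM, exceeded the succinate dehydrogenase gene sdhA, at 31.1, 48.9-fold. The 9 hydrogenase 3 genes of the list ranged from hycB at 0.120 to hycI at 28.0 RPKM, all below the median of all features. In this paragraph cydB, cyoB, sdhA, hycB and hycI were named after their values were seen.

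Amino acid biosynthesis genes lay around the median of all features, and none of their 8 lists was called in either direction. Of 90 such genes, 42 lay above and 48 below that median. Branched-chain genes had a median of 19.7 RPKM, from leuC at 7.75 to ilvN at 82.8 and ilvB at 66.4, with ilvD at 23.3 (percentile 19.3). Arginine genes had a median of 12.1 RPKM (argD), with argE at 119, argG at 46.3 and argF listed at 0 (12.6). Methionine genes had a median of 26.9 RPKM, from metF at 5.27 to metH at 104, with metB at 38.3 and metC at 37.2 (33.6). Cysteine and sulfate assimilation genes had a median of 6.29 RPKM, with cysI at 6.14 and the transporter gene cysU at 0.740, but cysK at 341 and cysE at 296 stood above (1.74). That list was called low when features under an RPKM of 1 (0.52) or listed at 0 (0.72) were left out. Against random runs of adjacent genes it lay at 6.14 and was not called. Histidine genes had a median of 53.8 RPKM, from hisH at 17.3 to hisI at 276, with hisG at 92.1 and hisC at 38.6 (58.2). Tryptophan and aromatic genes had a median of 56.1 RPKM (aroF), from the anthranilate synthase gene trpE at 2.12 to aroK at 476 and aroB at 460 (62.2). Threonine, lysine and proline genes had a median of 103 RPKM, from lysA at 4.33 to dapA at 990 and dapD at 675, with dapB at 91.4 (88.7). Glutamate, serine and glycine genes had a median of 107 RPKM, with the glutamine synthetase gene glnA at 1872, glyA at 1443, gltD at 97.5 and serB listed at 0 (86.4). The members dapA, dapD and glyA also serve cell wall and one-carbon metabolism. Purine and pyrimidine genes had a median of 119 RPKM, from purE, listed at 0, to purA at 1202, with purD at 113 (97.1).

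Genes that break down amino acids were high as a list, with a median of 662 RPKM and 17 of 24 members above the median of all features (percentile 100). The tryptophanase gene tnaA was at 10983 RPKM, the serine transporter gene sdaC was at 697, and the arginine degradation gene astE was at 0.290 RPKM. The aspartase gene aspA, at 6355 RPKM (95% Poisson interval 6321 to 6388), and the asparaginase gene ansB, at 5050, were named after their values were seen. Peptide and amino acid transporters were not called. Their median was 41.4 RPKM (43.8), and they ran from the branched-chain transporter gene livH at 0.670 to the oligopeptide-binding protein gene oppA at 2736, with artJ at 52.3. The labels name both LB and minimal medium for the cultures, and these values were not used to assign a medium.

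Operons for different carbon sources stood at different levels. Whether any of them responded to its sugar was not tested, as the series has 1 group. The galactitol operon had the highest median of the 52 lists, 5549 RPKM, with gatA at 5346, gatB at 10407 and gatD at 666 (percentile 100). The list for glycerol, galactose, ribose and trehalose had a median of 652 RPKM, with 20 of 22 members above the median of all features, from mglC at 25.4 to the trehalose transporter gene treB at 3407, and galM at 538 (100). The maltose regulon had a median of 309 RPKM, from malS at 22.9 to the maltose-binding protein gene malE at 1965, with malK at 263 (99.6, or 96.5 and not called against random runs of adjacent genes). Operons for lactose, arabinose, xylose, rhamnose and fucose had a median of 9.37 RPKM, from rhaA at 1.06 to fucU at 57.3, with araA at 9.45. Their list was not called (1.29, or 6.45 against random runs of adjacent genes). It was called low under 3 of the other settings tried (0.03 to 0.73). The list named silent beta-glucoside, propionate and phenylacetate operons, which also holds mhp and hca genes, was called low (percentile 0). Its name was set before the data were examined and is not a result. The list had a median of 1.32 RPKM (paaB), none of 29 members above the median of all features, mhpB at 0.210 and hcaF at 11.96. Fatty acid degradation genes had a median of 20.8 RPKM (fadJ), from fadE at 1.47 to the outer membrane transporter gene fadL at 393, and were not called (27.0).

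The remaining low lists concerned motility and nutrient starvation. Of 43 flagella and chemotaxis genes, only the master regulator genes flhC at 62.8 and flhD at 48.2 RPKM exceeded the median of all features. Their median was 4.03 RPKM (flgH) and flgB was listed at 0 (percentile 0); flhD was named after its value was seen. Phosphate starvation genes had a median of 2.91 RPKM, with pstB at 59.4, phnL at 0.870 and phnG listed at 0 (0.01). With features under an RPKM of 1 left out, the phosphate list was no longer called (3.71). Iron uptake genes had a median of 8.02 RPKM, from fepG at 0.400 (about 0.147 to 0.870 by counting error) to the ferrous iron transporter gene feoA at 293, with entF at 8.73 (0.37, or 2.57 and not called against random runs of adjacent genes). Type 1 fimbriae and curli genes had a median of 7.52 RPKM, with fimA at 939, csgG at 5.91 and csgF listed at 0 (2.08). Rac and e14 prophage genes had a median of 7.40 RPKM, from kilR at 0.320 to the repressor gene racR at 639, with mcrA at 7.09 (3.15). Neither of these last lists was called.

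Among stress lists, cold shock, heat shock and oxidative stress were called high. These calls are against random genes of the same transcriptome and do not show that a stress response was induced. The 10 cold shock genes had a median of 1401 RPKM, with cspA at 64477, cspB at 1614 and cspI listed at 0 (percentile 100). Another member, cspG, was at 15319 RPKM (95% Poisson interval 15184 to 15454) and was named after its value was seen. Heat shock genes had a median of 369 RPKM, with the chaperonin gene groS at 1232, htpG at 443 and the small heat shock protein gene ibpB at 15.9 (99.99). Oxidative stress genes had a median of 281 RPKM (trxB), from soxR at 6.09 to the peroxidase gene ahpC at 11953 (99.79). Stationary phase and acid resistance genes were not called, with a median of 77.7 RPKM, dps at 1979, hdeB at 83.9 and gadB at 0.790 (82.1). SOS response genes were not called either, with a median of 47.9 RPKM, yebG at 588, dinB at 34.8 and dinI listed at 0 (53.1). Iron-sulfur cluster assembly genes had a median of 70.9 RPKM (hscB), from sufB at 19.6 to iscU at 580 (72.4). The 23 small and stable RNAs spanned the whole range, from micF, listed at 0, through rybB at 45.3 RPKM to ssrA, and their median was not called (53.0).

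Toxin and antitoxin genes of the same operon were at similar levels on average. Over 10 pairs, the antitoxin exceeded the toxin in 3 and the toxin the antitoxin in 7, with a mean log2 ratio of -0.04 ± 1.01 (SD over pairs; exact sign-flip permutation test, two-sided, p = 0.896). The ratio lay within 1.2-fold in 5 pairs: relB and relE (75.4 and 81.4 RPKM), mazE and mazF (70.8 and 71.5), yefM and yoeB (119 and 127), dinJ and yafQ (1084 and 1120), and prlF and yhaV (220 and 188). The largest excess of antitoxin was hicB, at 77.1 RPKM, over hicA, at 18.0. The largest excess of toxin was higB, at 81.0, over higA, at 22.1 RPKM. The other pairs were hipB and hipA (35.9 and 20.3), mqsA and mqsR (44.1 and 83.0) and chpS and chpB (8.48 and 11.96 RPKM). As lists, antitoxins had a median of 73.1 RPKM (73.1st percentile) and toxins a median of 81.2 RPKM (76.4th percentile).

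Members of an operon resembled each other more than random genes did, although several operons held genes at very different levels. Over 36 operons the median SD of log2(RPKM + 1) was 1.06, against a mean of 2.82 and a lowest value of 2.13 in 1000 random collections of the same sizes. Of the 36 operons, 17 were called even, among them 14 of the 33 operons whose members all had an RPKM of at least 1. The other 3, flgB-J, phn and paa, hold members under 1, where the pseudocount of 1 narrows the spread. With a pseudocount of 0.1 flgB-J (percentile 12.7) and phn (1.81) were not called, whereas alpha, at 1.01 before, was called (0.89). The count of 17 rests on random genes as the comparison: against runs of adjacent genes, which are often operons themselves, 1 operon was called even. Against sets drawn from the 100 features nearest in level, which have almost no spread by construction, the count was 0. Neighbouring genes in general were alike, with Spearman's rho of 0.54 across 3955 adjacent pairs (highest of 100 shuffles 0.03). Genes are not independent replicates, so no p-value is given.

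The last gene was lower than the first by more than 2-fold in 15 operons and higher by more than 2-fold in 12, on the log2(RPKM + 1) scale, and the median log2 ratio of last to first was -0.07. The operons described singly here were chosen after their values were seen. Some ribosomal protein operons were lower at their end, from rpsJ at 12517 to rpsQ at 2787 RPKM in S10, from rplN at 11982 to rpmJ at 2798 in spc, and from rplJ at 6724 to the RNA polymerase gene rpoC at 467 in beta. In beta the step lay between rplL, at 6875 RPKM, and rpoB, at 815, an 8.43-fold difference. The alpha operon (rpsM 3974, rplQ 3666) and the str operon (rpsL 2952, tufA 4591) differed by less than 2-fold between first and last gene. In the maltose transporter operon malE exceeded malG, at 100 RPKM, 19.4-fold on the log2(RPKM + 1) scale. The first gene of nuo, nuoA, was at 912 RPKM and the last, nuoN, at 190. Likewise given as first and last gene, the nitrate reductase operon had narG at 3371 and narI at 462 RPKM, and frd had frdA at 1522 and frdD at 455. In the same order, gat had gatY at 6936 and gatD at 666, and tna had tnaA at 10983 and tnaB at 1184. In opp and dpp the binding protein genes oppA at 2736 and dppA at 664 RPKM exceeded the membrane component genes oppB at 138 and dppC at 15.8, while the last genes oppF and dppF were at 892 and 161. The last gene was the higher in sdh-suc, from sdhC at 29.0 to sucD at 467 RPKM, in trp, from trpE at 2.12 to trpA at 37.8, and in the division and cell wall cluster, from mraZ at 760 to lpxC at 2054. The genes rplL, oppB and dppC were named after their values were seen.

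**Figure D3:**
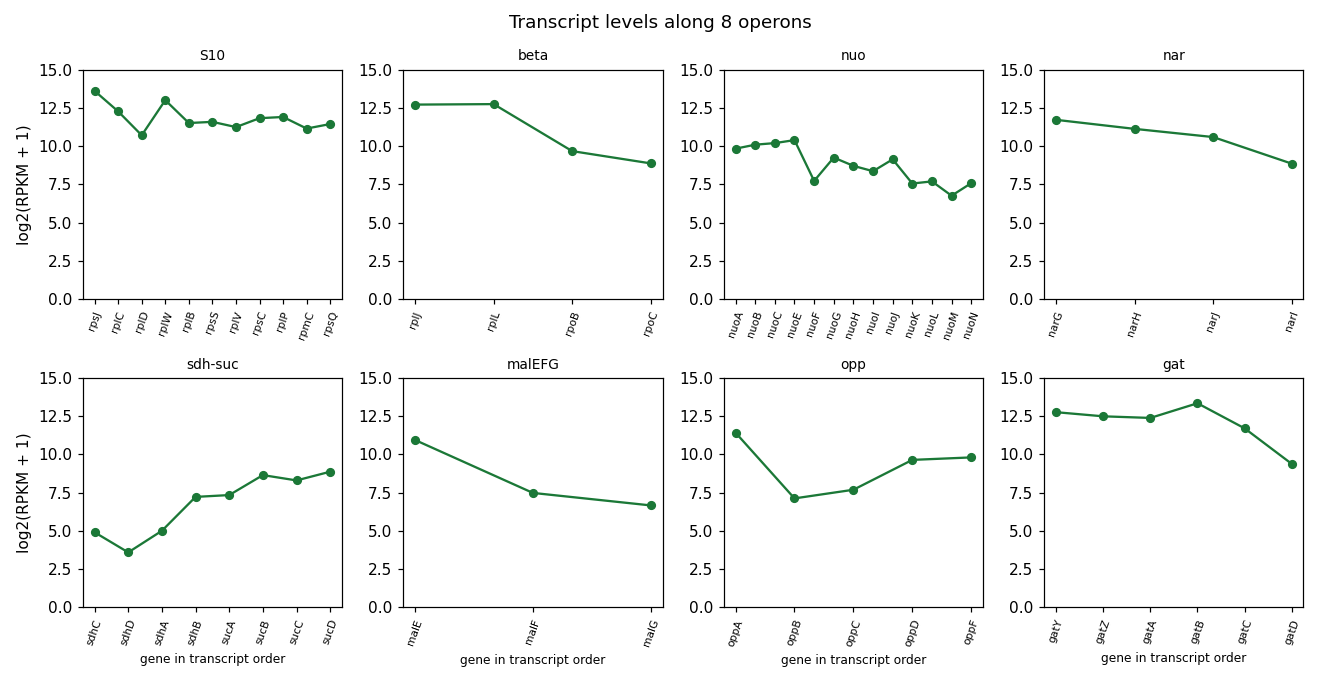
Transcript level as log2(RPKM + 1) on the vertical axis for each gene (points, joined in transcript order on the horizontal axis) of 8 operons chosen after their values were seen. The beta operon drops from rplL to rpoB, malEFG from malE to malF, and sdh-suc climbs from sdhD, at 11.1 RPKM, to sucD.

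Values of features that exist in several near-identical copies are uncertain. Of 64 transfer RNA genes, 29 were listed at 0 (45.3%, exact 95% interval 32.8 to 58.3), as were 4 of 13 ribosomal RNA genes, against 83 of 4095 protein-coding genes (2.03%, 1.62 to 2.51). Among features of up to 100 bases, which include all 64 transfer RNA genes, 6 of 39 protein-coding genes (15.4%, 5.86 to 30.5) and 5 of 23 non-coding RNA genes (21.7%, 7.46 to 43.7) were listed at 0. The ribosomal RNA genes, which had been depleted from the RNA, ranged from 0 to 511 RPKM. The elongation factor Tu genes tufA and tufB, which share nearly their whole sequence, were at 4591 and 1219 RPKM, and how reads were divided between such copies is not given in the sources used here. The gene tufB was named after its value was seen.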

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

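No alternative turned a list from high to low or the reverse, and 39 of the 52 lists kept their call under each alternative run. A pseudocount of 0.1 and random lists matched on gene length changed no list's call, nor did protein-coding features only for the 51 lists that this setting leaves. With features under an RPKM of 1 left out, the TCA cycle (98.46) and phosphate starvation (3.71) lost their calls, whereas sulfate assimilation (0.52) and the sugar operons (0.23) became low and anaerobic respiration (99.99) became high. Fewer features enter that comparison, and the cause was not tested further. With the mean of log2 values in place of the median, alternative sigma factors lost their call (93.66), glyoxylate shunt and gluconeogenesis (99.40) and the small RNAs (99.61) became high, and the sugar operons (0.03) and the Rac and e14 prophages (0.79) became low. With features listed at 0 left out, an alternative chosen after the data were examined, sigma factors fell just short (98.98), and sulfate assimilation (0.72) and the sugar operons (0.73) became low. Against random lists that keep runs of adjacent genes, also chosen after the data were examined, ATP synthase (98.6), NADH dehydrogenase I (97.755), the TCA cycle (94.32), the maltose regulon (96.48) and iron uptake (2.57) lost their calls, since operon members are alike. The share of the 10 highest features was 15.7% among protein-coding features alone, a set without the non-coding RNAs that make up 6 of the 10. Even operons numbered 16 with a pseudocount of 0.1 and 18 with members listed at 0 left out. They numbered 1 against runs of adjacent genes and 0 against the 100 features nearest in level, a comparison whose random sets have almost no spread by construction. The agreement between replicates and the results without each replicate were not run, because the table used here holds 1 value per feature, nor was the level by distance from the replication origin, which needs a named build. Depth limits the statements on genes under 1 RPKM, many of which rest on fewer than 10 reads.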

Other observations

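The tests of oxygen limitation and of cooling were set before their outcome was seen. Those of carry-over, of gene length for the cold shock genes, and of absent transcripts, fragment length and copies for the genes listed at 0 were chosen after results they bear on had been seen. Genes named here that the rule for named genes does not cover, among them pdxJ, tsaD and the examples from the set of 14 genes for the oxygen test, were chosen after their values were seen.

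Several further genes, chosen after their values were seen, stood out. The serine and threonine degradation operon tdc, which is known to be expressed without oxygen, ran from tdcA at 416 RPKM to tdcF at 1624. The glycine cleavage genes gcvT and gcvH were at 1435 and 2268 RPKM, with gcvP of the same operon lower, at 561. The glycyl radical cofactor protein gene grcA, which can restore pyruvate formate-lyase after damage by oxygen, was at 11327 RPKM, and the ribosome-associated factor gene raiA at 12502. Among regulatory RNAs, csrC and glmZ stood at 4019 and 3342 RPKM, whereas ryhB, a small RNA made under iron limitation, was at 6.84 RPKM. Other small RNAs were low too, such as dsrA at 2.35 and micA at 4.32 RPKM. Of the 23 small and stable RNAs, 12 lay above the median of all features. Loss of short RNAs stays open, so the value of ryhB was not read as a sign of iron status. The pyrimidine gene pyrE was at 2.80 RPKM (95% Poisson interval 1.85 to 4.07), while pyrG was at 714.

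The fermentation list was called high and narG and frdA stood at 3371 and 1522 RPKM, while sdhC, sdhD and sdhA stood at 29.0, 11.1 and 31.1 RPKM, below the median of all features, with sdhB at 148, and 4 of the 5 cyo genes stood above it but below cydA and cydB. The fixed anaerobic list was not called (percentile 96.6, or 88.4 against random runs of adjacent genes), with 26 of 47 members above that median. Its genes hyaA to hyaF (1.06 to 6.97 RPKM) and hycA to hycG (0.120 to 4.59), which are also known to be expressed without oxygen, were low. A candidate explanation of the pattern, despite these genes, is oxygen limitation at harvest. If so, other genes known to be activated without oxygen should be high too: 14 such genes outside the lists, among them nrdD at 667 and napA at 668 RPKM, and hybO, which shares an operon with listed genes, had a median of 288 RPKM, at the 99.83rd percentile of random lists (99.74 against random runs of adjacent genes), although dcuB at 18.3 and ynfE at 22.5 lay below the median of all features. This test separates little, because high percentiles were common among the gene lists. Of the 52 lists, 24 were called high, among them replication (99.9) and cell division and shape (99.98). The level of the 14 genes therefore does not single out oxygen limitation. RNA carried over from the overnight culture was left open by its test. The stationary phase list lay at the 82.1st percentile, between the bounds set for that test. Without an aerated reference culture the size of any response cannot be given, and growth conditions that the labels do not describe, such as nitrate in the medium, were not tested, nor was any biological explanation from the design, which has 1 group.

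The genes cspA, cspG and cspB, which are known to respond to cold, were at 64477, 15319 and 1614 RPKM in cultures labelled 37 °C. Cooling of the cells before lysis may have contributed: 4 other cold-induced genes, lpxP at 435, rbfA at 206, bipA at 594 and rhlE at 144 RPKM, had a median at the 95.96th percentile. That is a small set, and all but lpxP are also used at 37 °C, so the test is a weak one. Inflated RPKM of short genes stays open for the 3 as a set. The lowest of them, cspB, lay at the 90.4th percentile of protein-coding genes within 50 bases of its length, between the bounds set for the test. By the same measure cspG lay at the 98.1st percentile and cspA at the 100th. Genes of like length to these last had a median of 46.3 RPKM, so most short genes were far lower. Expression of these genes in cells growing at 37 °C, for which the design has no comparison, stays open and was not tested.

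Protein-coding genes listed at 0 numbered 83, and they included rpmA, ihfA, serB, pdxJ and tsaD. For each of the 80 with a neighbour in the table, the mean RPKM of its neighbours was taken, and the median of these means was 14.2 RPKM. That was 6.92-fold the same measure for protein-coding genes with 1 to 3 reads (2.06 RPKM), and above 99.5% of random draws of the latter. These levels argue against absence of transcripts for the set as a whole, but only indirectly, as a neighbour may belong to another transcript. Absence stays possible for part of the set, as the same measure for all protein-coding genes was 68.3 RPKM. Genes shorter than the 300-base fragments made up 38.8% of these 80, against 9.55% of all protein-coding genes, so length cannot be the whole cause. Whether reads that match near-identical copies were dropped stays open for these 80, of which 7 (8.75%) were insertion sequence genes or known copies. It also stays open for the 42.9% of transfer and ribosomal RNA genes listed at 0. Transfer RNA genes exceeded protein-coding genes of up to 100 bases (45.3% against 15.4%, intervals apart), so annotated gene length alone does not account for them. They did not exceed short non-coding RNAs beyond the intervals (21.7%, 7.46 to 43.7). Annotated length is not the length of the RNA molecule, so loss of short RNAs stays open. Of the 10 ribosomal RNA genes longer than the fragments 1 was at 0 (10%, 0.253 to 44.5).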
